A study of Mus musculus with 8 samples.

How the data were processed

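Total RNA from 8 mouse samples was labelled with biotin and hybridised to Affymetrix expression arrays, with 1 sample per array. Per the labels, cells were sorted from fresh tissue of Cx3cr1gfp/+ C57BL/6 mice after digestion with Collagenase VIII and antibody staining. The 4 sorted populations were F4/80-high tumour-associated macrophages and Ly6C-high tumour-infiltrating cells from orthotopic colorectal tumours (F4/80-high TAM and Ly6C-high TAM), steady-state lamina propria macrophages from colon (colon macrophages) and Ly6C-high monocytes from spleen (spleen monocytes). Each population had 2 arrays, numbered as replicates 1 and 2 in the labels. The sex labels differ between the replicates of colon macrophages (male and female) and of spleen monocytes (male and mixed), so these were not repeated arrays of the same RNA. For the tumour populations, all labelled male, the labels do not say whether replicates came from separate animals, pools or repeated arrays, so the p-values describe only the spread between these samples.

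The deposited values are log2 expression values that the authors made with RMA, per the labels' processing notes, which name Partek 6.6 and no version of RMA. RMA corrects the background, normalises between arrays and summarises probes into probe sets. The submitters compared all populations in pairs and selected genes at a false discovery rate of 5% and a fold change of 2 or more, per their design notes. The genome build was not given in the sources used here.

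The values came from the series matrix and covered 35556 probe sets on 8 arrays. Gene symbols came from a deposited annotated table, joined by probe set identifier. That table also holds 8 columns of values whose headings match no sample label. Those columns were not used here, although the planned analysis had named the table as the source of the values, so a comparison of the 2 sources of values could not be run. Of the probe sets, 24692 carried a symbol and 10864 did not. Symbols were updated through RefSeq accessions of the GRCm38.p6 annotation, which matched 21023 of the named probe sets and changed the symbol of 1926. The other 3669 kept the symbol of the annotated table. A gene with several probe sets was represented by the probe set with the highest mean over all arrays, which applied to 1901 of 21442 genes. For 36 probe sets the annotation named further genes. The number of arrays limits the precision of every value.

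Differences were fitted with limma 3.58.1 in R 4.3.3, with a mean per population, all 8 arrays in the fit and empirical Bayes moderation of the spread (4 residual and 2.64 prior degrees of freedom). P-values were adjusted over the 21442 genes within each comparison by the Benjamini-Hochberg method. A gene passed the threshold at an adjusted p of 0.05 or less and a fold of 2 or more, following the submitters' criteria. All 6 pairs of populations were compared. The difference between the 2 tumour differences (F4/80-high TAM minus colon macrophages, and Ly6C-high TAM minus spleen monocytes) was tested as an interaction at the same adjusted p without a fold limit. Every p-value printed here is a limma adjusted p unless another test is named. Errors of log2 differences are standard errors of the fit, and errors of group values are SD with n = 2.

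Gene lists were written before the data were examined, as were the comparisons, thresholds and other settings to be tried. There were 33 lists with 823 entries, of which 807 were measured. They comprised 7 lists of matrix genes, 13 of macrophage states and sort markers, 11 of other cell types and 2 for sample quality, and 32 lists had the 3 measured members needed for a test. Each list was tested against all other genes with camera at a preset correlation of 0.01 between genes, adjusted over the lists within a comparison, and again with a correlation estimated from the data. Counts of list members past the threshold are given over all genes and adjusted over the list alone.

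The genes named in the text followed a rule also fixed in advance. It took the 5 genes with the largest fold in each direction in the 3 main comparisons, among genes past the threshold whose groups did not overlap, and up to 4 members past the threshold from each matrix or state list. It took 3 genes in each direction for the other comparisons and for genes higher in 1 population than in the 3 others. Sort markers, collagens I, III, VI and XIV and sex-linked genes were to be named whatever their values, but not all of them are printed for every comparison. The most abundant markers of other cell types were chosen among those that passed the threshold in any comparison. Predicted or unnamed transcripts, and probe sets that named several genes, were skipped. Mela lay outside this rule and was chosen after its values were seen. Rankings of single genes by size in the text are among the genes that the rule allowed.

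The fit was tested on simulated data for F4/80-high TAM minus colon macrophages, with 200 of 21442 genes changed and 20 simulations. It recovered 79.8% of genes changed by 2.5-fold, 92.6% at 4-fold and 98.1% at 8-fold, with a mean of 7.5 false calls among 188 calls. A list of 30 genes shifted by 1 on the log2 scale was called in 20 of 20 simulations. The simulated genes varied independently of each other, so this does not cover lists whose genes vary together. Simulated populations without changes gave at most 2 calls in any direction of a comparison.

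The settings tried were quantile normalization, median centring, filters on weakly expressed genes, an intensity trend with robust spread, no moderation, fits of only the 2 groups compared, array weights, the mean over probe sets, a replicate block, a sex covariate, removal of the 846 genes on the sex chromosomes, other fold limits, adjustment over all 6 comparisons and the removal of each array. Further settings were chosen after the data had been seen. They were the removal of both tumour arrays of replicate 2, a replicate block for the tumour arrays alone, a block with the monocyte numbers crossed, and the mean of the fibroblast or epithelial markers as a covariate. A population left with a lone array adds nothing to the spread of a fit, so counts passing then rest on the spread of the other populations. Removing an array of a population outside a comparison alters that spread and not the difference. Figures were drawn with matplotlib 3.10.9.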

Results

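Gene expression was measured on 8 arrays in 4 populations of myeloid cells, with 2 arrays each, sorted from mice that carry a green fluorescent reporter in the fractalkine receptor gene Cx3cr1. F4/80-high TAM and Ly6C-high TAM came from orthotopic colorectal tumours, colon macrophages from healthy lamina propria, and Ly6C-high monocytes from spleen. The median log2 value over 35556 probe sets lay between 6.84 and 7.07, and was lowest in the replicate 2 arrays of F4/80-high TAM (6.84) and Ly6C-high TAM (6.90). Adgre1, which encodes F4/80, had log2 values of 12.40 ± 0.12 (SD, n = 2) in F4/80-high TAM, 11.54 ± 0.55 in Ly6C-high TAM, 12.88 ± 0.06 in colon macrophages and 12.04 ± 0.04 in spleen monocytes. Ly6c2, which encodes a Ly6C antigen, had 11.24 ± 0.47, 12.86 ± 0.21, 10.03 ± 0.19 and 12.92 ± 0.02 in the same order. Csf1r, the receptor for the macrophage growth factor CSF1, lay between 12.64 and 12.92 in the 4 populations. Xist, which is expressed from the inactive X chromosome, read 12.11 in the colon array labelled female, 10.04 in the monocyte array labelled mixed and 4.60 to 4.96 in the 6 arrays labelled male. No named probe set belonged to a Y-linked gene.

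The comparison of F4/80-high TAM with colon macrophages asked how F4/80-high macrophages of the tumour differ from those of the healthy gut wall. Arginase 1, Arg1, was 77-fold higher in the tumour macrophages (log2 difference 6.27 ± 0.14 SE, n = 2 per group, limma adjusted p = 4.71e-05), and the matrix glycoprotein osteopontin, Spp1, was 53.2-fold higher (5.73 ± 0.15). Interferon-response genes were higher as a group by camera at the preset correlation, as were classical monocyte genes, of which 10 of 24 passed, and both calls were lost with an estimated correlation (adjusted p = 0.592 for each). Fibronectin, Fn1, was higher by 11.3-fold. The anti-inflammatory cytokine Il10 was 18.9-fold lower (-4.24 ± 0.23, adjusted p = 0.00089). Over all genes, 573 were higher and 797 lower. With the epithelial marker mean as a covariate, a setting chosen after the data were seen, 2220 were higher and 1064 lower, of which 375 and 230 were shared with the fit without it. That mean was 10.42 and 11.16 in the colon arrays against 6.65 and 8.24 in the F4/80-high TAM arrays. As a covariate it also alters other differences from the colon arrays. Its counts in comparisons with colon macrophages are therefore not counts corrected for epithelial RNA. Without the replicate 2 arrays of both tumour populations, which carried the most fibroblast and epithelial marker signal of the tumour arrays, 784 were higher and 1006 lower, and 471 and 699 of these were shared with the full set. With each array left out in turn, the counts ran from 291 (without colon replicate 1) to 788 (without Ly6C-high TAM replicate 1) higher and from 319 (without F4/80-high TAM replicate 1) to 960 (without Ly6C-high TAM replicate 1) lower.

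Among the genes that the naming rule allowed, the next largest rises were in Trem1, an amplifier of inflammatory signalling (5.28 ± 0.20), and Slfn1, an interferon-inducible Schlafen gene (4.98 ± 0.28). Irg1, which makes itaconate, followed (4.42 ± 0.28). Of 38 interferon-response genes, 29 were higher and 0 lower, and 30 were higher when adjusted over the list alone (camera adjusted p = 3.42e-24, adjusted p = 0.592 with an estimated correlation). They included Ifi205 (12-fold), Oas3 (9.19-fold), Rsad2 (7.98-fold) and Usp18 (7.08-fold). The count of 29 fell to 22 without F4/80-high TAM replicate 1. Of 35 inflammatory cytokines and receptors, 7 were higher and 1 lower, the same numbers as when adjusted over the list alone, with no shift of the list by camera (adjusted p = 0.198). Nos2, the inducible nitric oxide synthase, was among them (3.16). Of 27 chemokines, 3 were higher and 1 lower (6 and 1 when adjusted over the list alone, camera adjusted p = 0.108), and 6 were higher without F4/80-high TAM replicate 1. Cxcl14 (2.79) and the interferon-inducible Cxcl11 (2.25) kept their calls with any array left out, while Cxcl1 (-1.74) lost its call without any of 6 arrays (adjusted p of up to 0.112). Among 34 hypoxia and glycolysis genes, 12 were higher and 0 lower (13 and 0 when adjusted over the list alone, camera adjusted p = 2.74e-07, adjusted p = 0.592 with an estimated correlation). Bnip3 (3.11), the lactate exporter Slc16a3 (2.95) and Ddit4 (1.89) led this group, and its count fell to 4 without colon replicate 1.

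Of 24 classical monocyte genes, 10 were higher and 1 lower (10 and 2 when adjusted over the list alone, camera adjusted p = 0.00512, adjusted p = 0.592 with an estimated correlation). Fn1 (3.50) kept its call with any array left out. S100a4 (3.39) and F10 (3.17) lost theirs without colon replicate 2, at adjusted p = 0.0506 and adjusted p = 0.0585, and the count then fell to 5. Of 31 resident gut macrophage genes, 2 were higher and 6 lower, the same numbers as when adjusted over the list alone (camera adjusted p = 0.00181, adjusted p = 0.592 with an estimated correlation). Il10 and the apolipoprotein gene Apol7c (-6.14 ± 0.79) were among those lower, and the count of lower genes fell to 2 without colon replicate 2. Of 12 genes of MHC class II presentation, 3 were lower and 0 higher (3 and 0 when adjusted over the list alone, camera adjusted p = 1.69e-05, adjusted p = 0.592 with an estimated correlation). The class II transactivator Ciita fell by 2.23 ± 0.26, and H2-Ob and H2-Eb1 fell by 1.65 and 1.04. This count was 1 without F4/80-high TAM replicate 1 and 5 without F4/80-high TAM replicate 2. Among 24 alternative activation genes, 3 were higher and 4 lower (3 and 5 when adjusted over the list alone). The mean of that list was 0.05, its median -0.12, and camera gave no shift (adjusted p = 0.285). The lipid receptor Trem2 was higher (1.83) and the scavenger receptor Cd36 lower (-2.33). Of 17 complement genes, 3 were higher and 0 lower (4 and 0 when adjusted over the list alone, camera adjusted p = 0.0515), led by complement factor B, Cfb (2.21). Among the sort markers fixed by the naming rule, Ly6c2 was higher (1.21 ± 0.24, limma adjusted p = 0.0236). Adgre1 (-0.475), Ly6c1 (0.91), Cx3cr1 (-0.42), Ccr2 (-0.14), Csf1r (-0.16) and H2-Ab1 (-0.92) did not pass the threshold.

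Of 38 collagen genes, 1 was higher and 0 lower (1 and 0 when adjusted over the list alone, camera adjusted p = 0.876). This was Col14a1, a fibril-associated collagen, which was 3.26-fold higher (1.71 ± 0.14, adjusted p = 0.00212) and passed with any array left out. The fibrillar collagens Col1a1 (0.49 ± 0.62, adjusted p = 0.73), Col1a2 (0.65) and Col3a1 (0.13) and the microfibrillar collagens Col6a1 (1.00), Col6a2 (0.72) and Col6a3 (0.25) did not pass. Without F4/80-high TAM replicate 2, the difference was -0.24 for Col1a1, -0.21 for Col1a2, -0.19 for Col3a1 and -0.17 for Col6a3. Quantile normalization gave -0.016 for Col3a1. Of 46 matrix glycoproteins and proteoglycans, 4 were higher and 1 lower (the same when adjusted over the list alone, camera adjusted p = 0.139). The large proteoglycan versican, Vcan, was higher (2.45), but lost its call without either colon array (adjusted p of up to 0.0898). Of 27 genes for collagen processing and crosslinking, 2 were higher and 0 lower (2 and 0 when adjusted over the list alone, camera adjusted p = 0.0368, adjusted p = 0.835 with an estimated correlation). They were the lysyl hydroxylase Plod1 (1.21) and the transglutaminase Tgm2 (2.83-fold), and Tgm2 lost its call without either colon array (adjusted p of up to 0.0616). Of 34 matrix proteases, 2 were higher and 2 lower (the same when adjusted over the list alone, camera adjusted p = 0.319). The membrane proteases Adam8 (3.86 ± 0.19, 14.5-fold) and Adam19 (-3.33 ± 0.13, 10.1-fold lower) moved apart, and both passed with any array left out.

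Besides Apol7c, the genes with the largest falls that the naming rule allowed were genes of the gut mucosa. Mptx1, a mucosal pentraxin, fell by 6.71 ± 0.49, the goblet cell gene Clca1 fell by 6.54 ± 0.76, and Cyp2c55, a colonic cytochrome, fell by 6.17 ± 0.43. The carbonic anhydrase Car1 fell by 5.71 ± 1.26, but lost this call without any of 6 arrays (adjusted p of up to 0.142). Of 25 epithelial and tumour cell markers, 17 were lower and 0 higher (23 and 0 when adjusted over the list alone, camera adjusted p = 1.51e-17, adjusted p = 0.592 with an estimated correlation). The mean log2 value of this list was 10.42 and 11.16 in the colon arrays, 6.65 and 8.24 in the F4/80-high TAM arrays and 6.77 and 6.25 in spleen monocytes. The count of lower markers fell to 5 without F4/80-high TAM replicate 1. Of 24 fibroblast markers outside the matrix, 3 were higher and 1 lower (4 and 1 when adjusted over the list alone, camera adjusted p = 0.653). Pdpn, which fibroblasts share with inflammatory macrophages, was the most abundant of them (3.15). Cell cycle genes were higher as a list (3 of 40 higher and 0 lower, 2 and 0 when adjusted over the list alone, camera adjusted p = 4.26e-08, adjusted p = 0.746 with an estimated correlation). The count fell without F4/80-high TAM replicate 1. It rose without Ly6C-high TAM replicate 1, but that removal left each difference unchanged. It altered only the spread of the fit, which held the gap between the Ly6C-high TAM replicates (list means of 8.03 and 9.66). Smooth muscle and pericyte markers were lower as a list (1 of 14 passing, camera adjusted p = 0.00761, adjusted p = 0.746 with an estimated correlation), and the other 8 lists of other cell types were not shifted. Immediate early genes, which respond to tissue dissociation, were lower (3 of 26 lower and 0 higher, 3 when adjusted over the list alone, camera adjusted p = 1.29e-06, adjusted p = 0.724 with an estimated correlation), and none passed without F4/80-high TAM replicate 1.

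**Figure D1:**
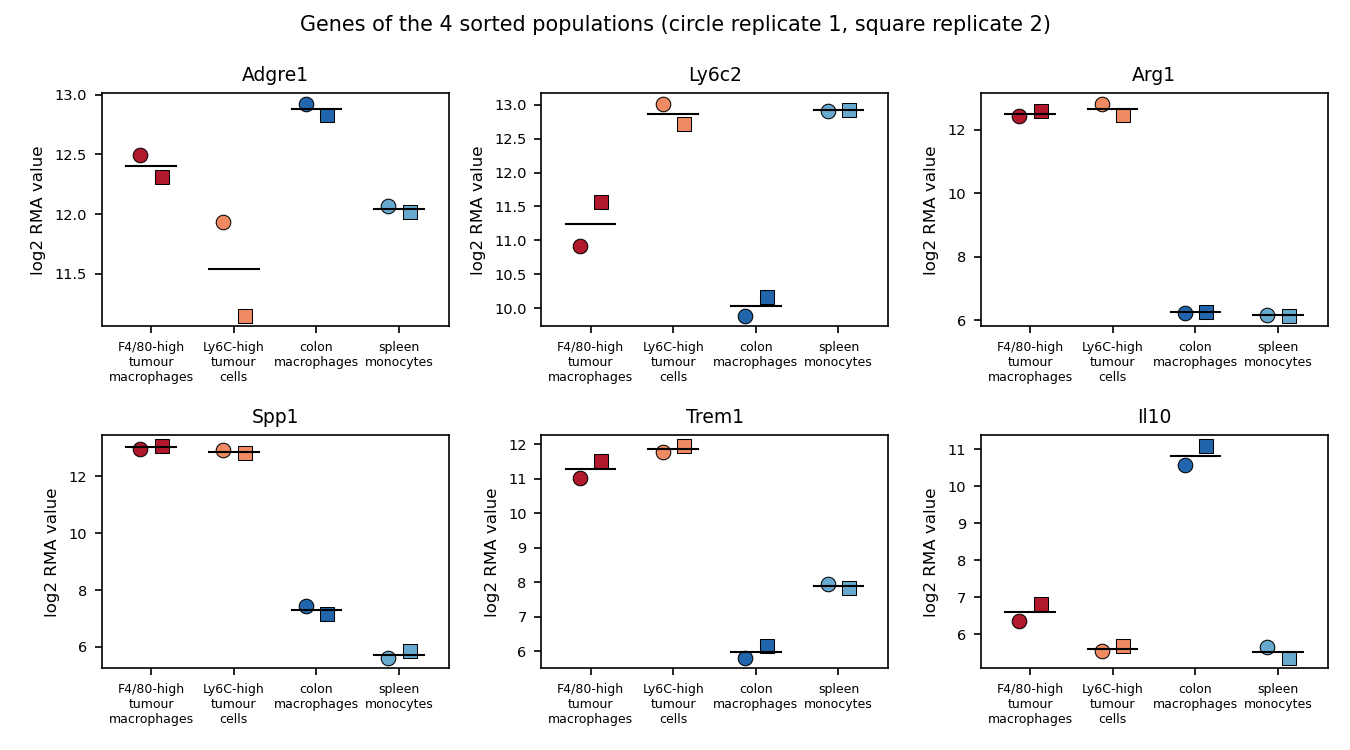
Log2 RMA values (y axis) of 6 genes in the 4 sorted populations (x axis). Each point is an array, with circles for replicate 1 and squares for replicate 2, and each line is the mean of the 2 arrays. Arg1 and Spp1 were higher on all 4 tumour arrays than on the colon and spleen arrays, while Il10 was lower on the F4/80-high TAM arrays than on the colon arrays.

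The comparison of F4/80-high TAM with Ly6C-high TAM asked what distinguishes the 2 populations sorted from tumours. The F4/80-high cells had 8.78-fold more Fcrls (3.13 ± 0.36 SE, n = 2 per group, limma adjusted p = 0.0372) and 6.53-fold more of the folate receptor Folr2 (2.71 ± 0.28, adjusted p = 0.0324), both genes of tissue macrophages. Col14a1 was 4.26-fold higher (2.09 ± 0.14, adjusted p = 0.00845). Classical monocyte genes were lower as a group, and the serpin Serpinb10 was 22.7-fold lower (-4.51 ± 0.24, adjusted p = 0.00597). In all, 36 genes were higher and 21 lower, with 1837 genes at an unadjusted p under 0.05. A replicate block for the tumour arrays alone, chosen after the data were seen, gave more genes in both directions. Median centring gave 26 higher and 27 lower, and quantile normalization 26 and 25. A fit without the replicate 2 arrays of both tumour populations left a lone array in each. Its spread came from the colon and spleen replicates. There 371 and 76 genes differed 2-fold or more, against 768 and 1536 between the F4/80-high and Ly6C-high TAM replicates. A count from that fit would therefore not show how many genes separate the 2 populations. No gene passed in limma without F4/80-high TAM replicate 1, and 190 were higher and 55 lower without Ly6C-high TAM replicate 2.

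Lilra5 (2.37), the vesicle protein gene Scamp5 (2.27) and the adhesion gene Cadm1 (2.25 ± 0.15, adjusted p = 0.00937) were the other genes with the largest rises. Adgre4, an adhesion receptor of monocytes, fell by 2.75, the phospholipase Plcb1 fell by 2.57, the triglyceride enzyme Dgat2 fell by 2.43 and the membrane protein gene Ifitm6 fell by 2.37. Each gene named here that passed lost its call without F4/80-high TAM replicate 1, Col14a1 at an adjusted p of 0.0617 at the highest and Serpinb10 at 0.0582. Of 24 classical monocyte genes, 3 were lower and 0 higher (13 and 0 when adjusted over the list alone, camera adjusted p = 6.05e-27). This was the list whose shift also passed with an estimated correlation (adjusted p = 0.0384). The populations were sorted by F4/80 and Ly6C, a marker of classical monocytes, so the sort itself favours this direction. The shift is therefore not independent of how the populations were defined. Ifitm6 and the neutrophil antigen Cd177 (-2.34) were among the members past the threshold. None passed in limma without F4/80-high TAM replicate 1, 8 were lower without F4/80-high TAM replicate 2, and 13 without the replicate 2 arrays of both tumour populations. Of 31 resident gut macrophage genes, 1 was higher and 0 lower (7 and 1 when adjusted over the list alone, camera adjusted p = 1.95e-06, adjusted p = 0.129 with an estimated correlation). The platelet factor gene Pf4 (1.49) was the chemokine that passed, and the integrin Itga9 (1.92) and the lectin receptor Cd22 (1.73) were also higher. Among the sort markers, Adgre1 differed by 0.86 ± 0.24 (adjusted p = 0.312), Ly6c2 by -1.62 ± 0.24 (adjusted p = 0.0666), Ly6c1 by -1.69 ± 0.27 (adjusted p = 0.0866), Cx3cr1 by 1.56 (adjusted p = 0.348) and the chemokine receptor Ccr2 by -1.75 (adjusted p = 0.104). With the replicate block for the tumour arrays alone, Ly6c2, Ly6c1, Cx3cr1 and Ccr2 passed. That block pairs arrays by a number that the labels do not tie to an animal.

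Several lists were shifted by camera at the preset correlation with no member past the threshold. Cell cycle genes had a median of 1.02 over 40 genes (0 higher, 1 when adjusted over the list alone, camera adjusted p = 1.81e-12, adjusted p = 0.626 with an estimated correlation). Their mean log2 value was 9.67 and 10.002 in F4/80-high TAM replicates 1 and 2, against 8.03 and 9.66 in Ly6C-high TAM replicates 1 and 2. Of these genes 28 were higher without Ly6C-high TAM replicate 2, and 23 without the replicate 2 arrays of both populations. Interferon-response genes had a median of -0.45 over 38 genes (0 passing, camera adjusted p = 6.46e-21, adjusted p = 0.411 with an estimated correlation). Inflammatory cytokines and receptors (-0.42, 2 lower when adjusted over the list alone, adjusted p = 1.04e-06) and matrix glycoproteins (-0.44, 2 lower when adjusted over the list alone, adjusted p = 1.92e-08) were lower in the same way, at adjusted p = 0.608 and adjusted p = 0.626 with an estimated correlation. Of 38 collagens, Col14a1 passed (camera adjusted p = 0.309), and the list's median of 0.02 was -0.05 after median centring and after quantile normalization. Col1a1 (-0.70), Col1a2 (-0.62), Col3a1 (-0.70), Col6a1 (-0.51), Col6a2 (-0.56) and Col6a3 (-0.60) did not pass. Without F4/80-high TAM replicate 1 the differences were 0.03 for Col1a1 and 0.23 for Col1a2. The fibroblast markers had a median of -0.33 (0 of 24 passing, camera adjusted p = 0.000835, adjusted p = 0.626 with an estimated correlation), as did the epithelial markers (0 of 25 passing, camera adjusted p = 0.0212, adjusted p = 0.757 with an estimated correlation).

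**Figure D2:**
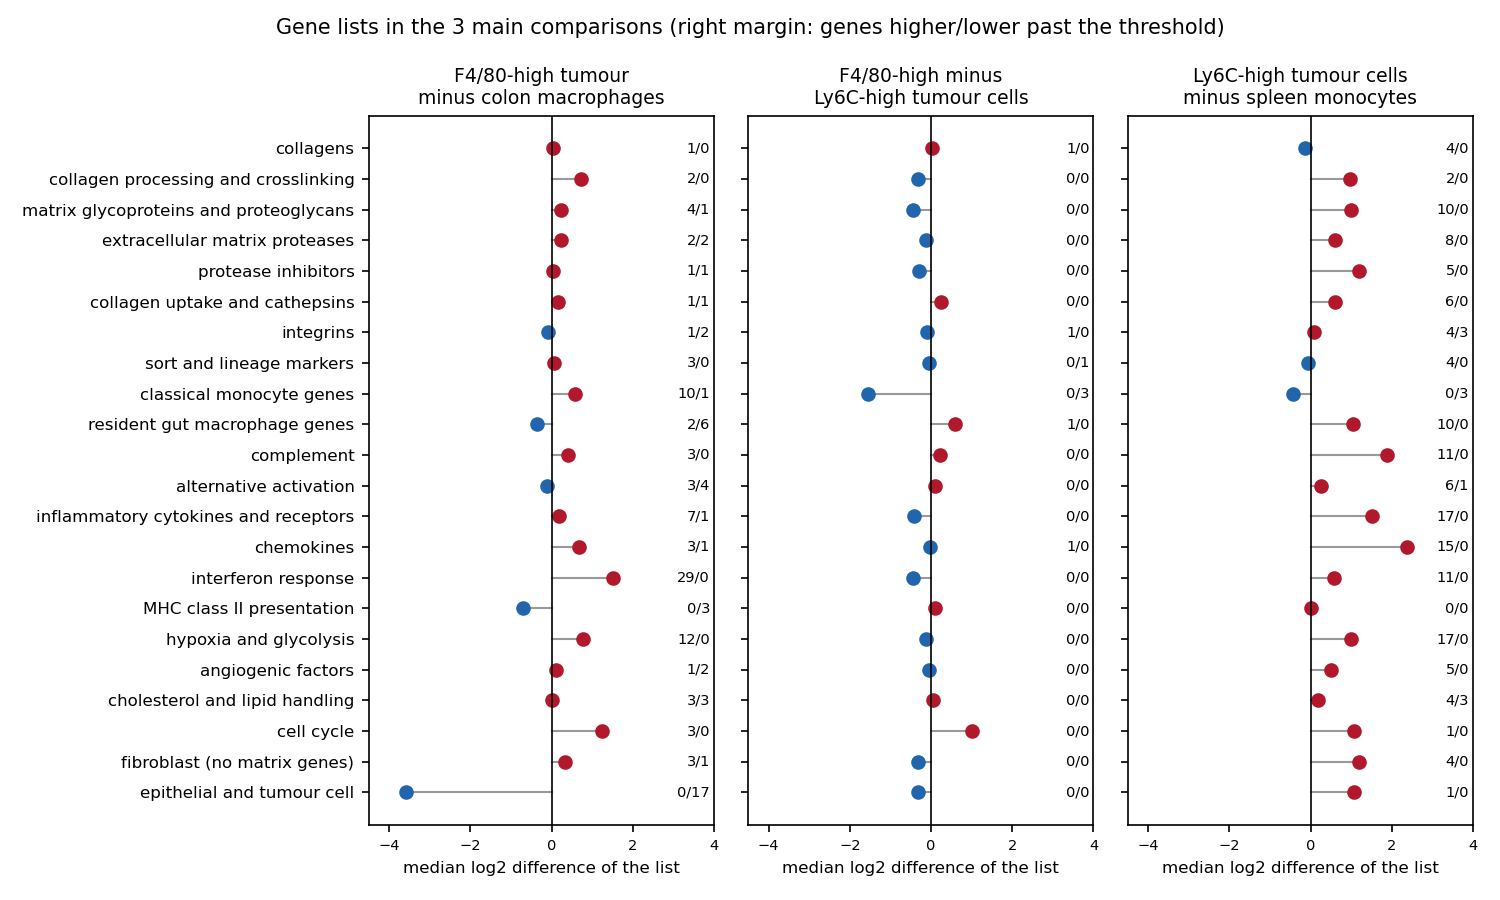
Median log2 difference (x axis) of each gene list (y axis) in the 3 main comparisons, with red points above 0 and blue points below. The numbers at the right margin are list members higher and lower past the threshold. Interferon-response genes were higher in F4/80-high TAM than in colon macrophages (29 of 38), classical monocyte genes were lower in F4/80-high than in Ly6C-high TAM, and chemokines were higher in Ly6C-high TAM than in spleen monocytes (15 of 27).

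The comparison of Ly6C-high TAM with spleen monocytes asked how Ly6C-high cells of the tumour differ from those of the spleen. Spp1 was 141-fold higher in the tumour cells (7.14 ± 0.15 SE, n = 2 per group, limma adjusted p = 1.86e-05) and Arg1 90.7-fold (6.50 ± 0.14, adjusted p = 1.86e-05). Matrix proteases, complement genes, chemokines, inflammatory cytokines and hypoxia genes were higher as groups by camera at the preset correlation, and each of these calls was lost with an estimated correlation (adjusted p = 0.182, 0.106, 0.106, 0.138 and 0.146). The small proteoglycans Bgn (6.07 ± 0.56) and Dcn (6.01 ± 0.44), which are also abundant in fibroblasts, were 67.3-fold and 64.5-fold higher, together with fibroblast markers. The transcription factor Spic, needed by red pulp macrophages, was 17.7-fold lower (-4.14 ± 0.20). In total 617 genes were higher and 347 lower, while median centring, which moved the median of all genes by -0.16, gave 575 and 505. Without the replicate 2 arrays of both tumour populations 798 were higher and 325 lower, of which 547 and 261 were shared with the full set. With each array left out in turn, the counts ran from 243 (without monocyte replicate 2) to 1680 (without Ly6C-high TAM replicate 1) higher and from 123 (without monocyte replicate 1) to 856 (without Ly6C-high TAM replicate 1) lower.

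Genes of matrix proteolysis were higher in the tumour cells. Of 34 matrix proteases, 8 were higher and 0 lower (12 and 0 when adjusted over the list alone, camera adjusted p = 1.14e-09, adjusted p = 0.182 with an estimated correlation). The membrane collagenase Mmp14 was 16.8-fold higher (4.07 ± 0.21), the macrophage elastase Mmp12 15.9-fold (3.99 ± 0.25), Adam8 11.3-fold (3.50 ± 0.19) and the plasminogen activator Plau 9.42-fold (3.24 ± 0.17), each with any array left out. The count was 5 without monocyte replicate 2, 15 without Ly6C-high TAM replicate 1 and 11 without the replicate 2 arrays of both tumour populations. Of 17 protease inhibitors, 5 were higher and 0 lower (6 and 0 when adjusted over the list alone, camera adjusted p = 2.79e-07, adjusted p = 0.24 with an estimated correlation), with 2 without monocyte replicate 1 and 9 without Ly6C-high TAM replicate 1. Spint1 (4.85) passed with any array left out, whereas Timp1 (5.43 ± 0.95) lost its call without any of 5 arrays (adjusted p of up to 0.144). Of 18 genes for collagen uptake and cathepsins, 6 were higher and 0 lower, as when adjusted over the list alone (camera adjusted p = 5.24e-06, adjusted p = 0.132 with an estimated correlation), with 3 without monocyte replicate 1. The scavenger receptor Stab1 (4.19) and the lysosomal protease Ctsl (2.85) kept their calls, and the collagen receptors Mrc1 (2.06) and Mrc2 (1.61) lost theirs without any of 4 and 5 arrays (adjusted p of up to 0.199 and 0.172). Among 25 integrins, 4 were higher and 3 lower (the same when adjusted over the list alone, camera adjusted p = 0.117), with the laminin receptor subunit Itga6 higher (4.37) and the leukocyte subunit Itgal lower (-1.70).

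Of 46 matrix glycoproteins and proteoglycans, 10 were higher and 0 lower (18 and 0 when adjusted over the list alone, camera adjusted p = 1.51e-15, adjusted p = 0.3 with an estimated correlation), and 16 were higher without the replicate 2 arrays of both tumour populations, 6 without monocyte replicate 1 and 29 without Ly6C-high TAM replicate 1. Sparc was 35.9-fold higher (5.17 ± 0.83), but lost its call without either monocyte array (adjusted p of up to 0.123). Of 27 genes for collagen processing and crosslinking, 2 were higher and 0 lower (5 and 0 when adjusted over the list alone, camera adjusted p = 1.8e-07, adjusted p = 0.38 with an estimated correlation), with 1 without colon replicate 1 and 15 without Ly6C-high TAM replicate 1. Tgm2 (4.28) kept its call with any array left out, and Pcolce (3.70), the enhancer of procollagen cleavage, lost it without any of 5 (adjusted p of up to 0.255). Of 38 collagens, 4 were higher and 0 lower (4 and 0 when adjusted over the list alone), with no shift of the list by camera (adjusted p = 0.173), whose median of -0.14 and mean of 0.38 differed in sign. The count was 1 without colon replicate 1, 12 without Ly6C-high TAM replicate 1 and 5 without the replicate 2 arrays of both tumour populations. Col14a1 (1.99 ± 0.14, 3.98-fold) passed with any array left out. Col6a1 (1.98 ± 0.41, 3.95-fold), Col6a2 (1.70 ± 0.30) and Col3a1 (1.70 ± 0.29) each lost their call without any of 5 arrays, at adjusted p of up to 0.234, 0.164 and 0.153. Col1a1 (1.94 ± 0.62, adjusted p = 0.134), Col1a2 (2.02 ± 0.66, adjusted p = 0.142) and Col6a3 (1.45, adjusted p = 0.112) did not pass.

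Markers of other cells moved with these genes. Of 24 fibroblast markers outside the matrix, 4 were higher and 0 lower (7 and 0 when adjusted over the list alone, camera adjusted p = 6.97e-08, adjusted p = 0.3 with an estimated correlation), among them Pdpn (3.98) and Islr (2.70). The count was 2 without colon replicate 1, 15 without Ly6C-high TAM replicate 1 and 6 without the replicate 2 arrays of both tumour populations. The mean log2 value of the list was 7.26 and 8.22 in the Ly6C-high TAM arrays, 7.11 and 7.76 in the F4/80-high TAM arrays, 6.95 and 7.01 in colon macrophages and 6.45 and 6.47 in spleen monocytes, so replicate 2 was higher than replicate 1 in both tumour populations. With the fibroblast marker mean as a covariate, 1 collagen was higher and 1 lower, and 6 matrix glycoproteins were higher and 6 lower, while 6 proteases were higher and 0 lower. Epithelial markers were higher as a list (1 of 25 passing, camera adjusted p = 0.000171, adjusted p = 0.532 with an estimated correlation). Their mean was 6.77 and 8.71 in the Ly6C-high TAM arrays, and their median difference was 1.07 with all arrays and 0.03 without the replicate 2 arrays of both tumour populations. Endothelial markers were also shifted (0 of 20 passing, camera adjusted p = 0.000591, adjusted p = 0.518 with an estimated correlation).

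**Figure D3:**
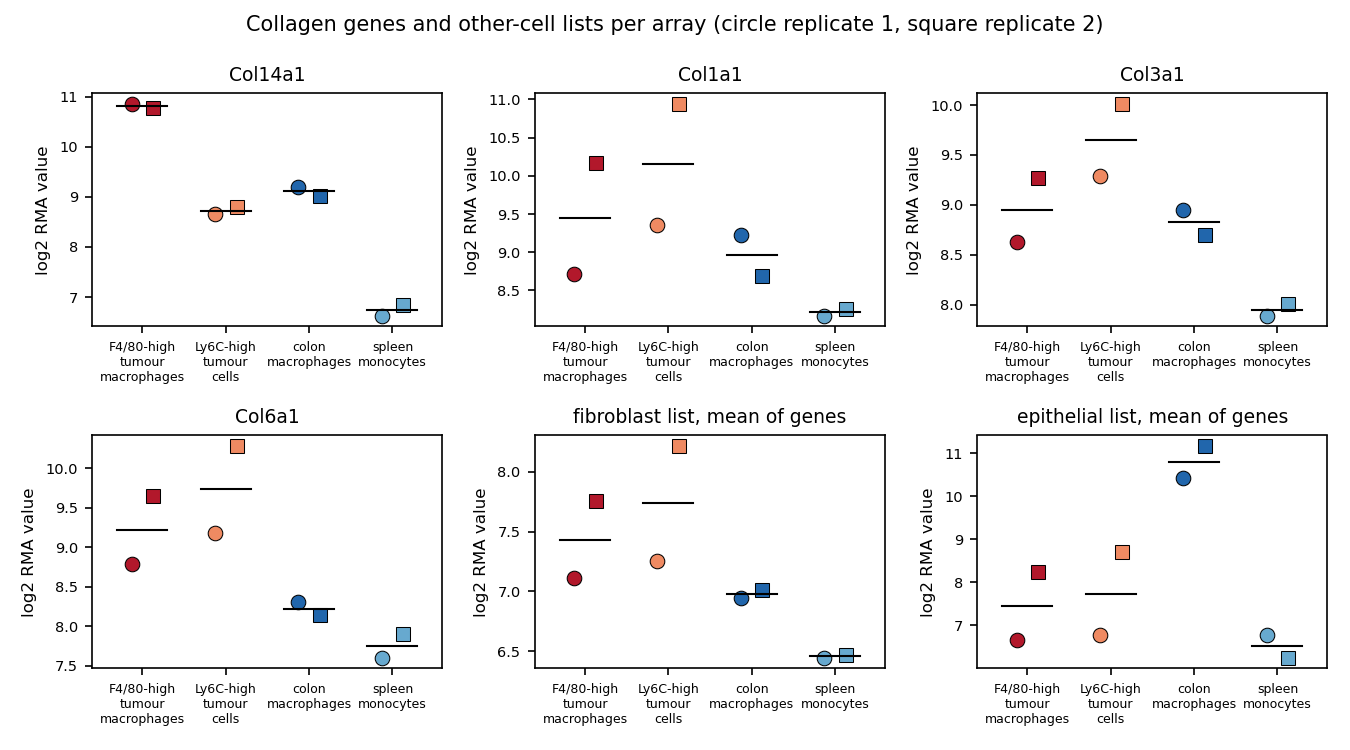
Log2 RMA values (y axis) of 4 collagen genes and the mean over the fibroblast and epithelial lists in the 4 populations (x axis). Points are arrays, with circles for replicate 1 and squares for replicate 2, and lines are means of the 2 arrays. Col1a1, Col3a1, Col6a1 and both lists were higher in replicate 2 than in replicate 1 of both tumour populations, whereas Col14a1 differed between replicates by -0.06 in F4/80-high TAM and 0.15 in Ly6C-high TAM.

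Complement, chemokine, cytokine and hypoxia genes were higher in Ly6C-high TAM. Of 17 complement genes, 11 were higher and 0 lower (12 and 1 when adjusted over the list alone, camera adjusted p = 1e-12, adjusted p = 0.106 with an estimated correlation). C3ar1 (4.37), C1qa (3.73), C1qc (3.63) and C1qb (3.21) led this list, and 7 were higher without monocyte replicate 2. Of 27 chemokines, 15 were higher and 0 lower (17 and 0 when adjusted over the list alone, camera adjusted p = 8.93e-18, adjusted p = 0.106 with an estimated correlation). The monocyte attractant Ccl7 (4.70 ± 0.18) and Pf4 (3.76) kept their calls with any array left out, and Ccl2 (3.95) and the neutrophil attractant Cxcl2 (4.76) lost theirs without Ly6C-high TAM replicate 2, among others (adjusted p of up to 0.0835 and 0.135). Of 35 inflammatory cytokines and receptors, 17 were higher and 0 lower (21 and 0 when adjusted over the list alone, camera adjusted p = 1.86e-17, adjusted p = 0.138 with an estimated correlation), including Il1a (5.95 ± 0.53, 61.8-fold), Irg1 (4.85) and Trem1 (3.96). The count fell to 7 without monocyte replicate 2. Of 34 hypoxia and glycolysis genes, 17 were higher and 0 lower, as when adjusted over the list alone (camera adjusted p = 1.86e-17, adjusted p = 0.146 with an estimated correlation). The vascular growth factor Vegfa was 28.6-fold higher (4.84 ± 0.35), and the oxygen sensor Egln3 (3.68) and glucose transporter Slc2a1 (2.49) were also higher, while the count fell to 6 without monocyte replicate 1. Of 31 angiogenic factors, 5 were higher and 0 lower (8 and 1 when adjusted over the list alone, camera adjusted p = 1.05e-05, adjusted p = 0.3 with an estimated correlation), among them Tgfb3 (3.51), Thbs1 (2.89) and Pdgfa (2.21). Without Ly6C-high TAM replicate 1, 14 were higher.

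Of 31 resident gut macrophage genes, 10 were higher and 0 lower (15 and 0 when adjusted over the list alone, camera adjusted p = 4.13e-07, adjusted p = 0.106 with an estimated correlation), with the tetraspanin Cd63 (3.83) and the chemokine Ccl24 (3.62) among them. The efferocytosis receptor Mertk (3.67) and the lipopolysaccharide receptor Cd14 (2.68) were higher, and Mertk lost its call without monocyte replicate 2 (adjusted p = 0.0592). Of 24 classical monocyte genes, 3 were lower and 0 higher (4 and 0 when adjusted over the list alone, camera adjusted p = 0.0205, adjusted p = 0.301 with an estimated correlation). None was lower without monocyte replicate 1, and 6 without Ly6C-high TAM replicate 1. Ly6c2 (-0.06), Ly6c1 (-0.05), Ccr2 (-0.46) and Adgre1 (-0.50) did not pass, and without Ly6C-high TAM replicate 2 the differences of Ly6c2 and Ly6c1 were 0.086 and 0.018. Of 24 alternative activation genes, 6 were higher and 1 lower (7 and 2 when adjusted over the list alone, camera adjusted p = 0.000987, adjusted p = 0.24 with an estimated correlation), led after Arg1 by Socs2 (5.19). Of 38 interferon-response genes, 11 were higher and 0 lower (12 and 0 when adjusted over the list alone, camera adjusted p = 3.47e-15, adjusted p = 0.264 with an estimated correlation), including Gbp6 (3.06) and Ifi44 (2.69), and the count fell to 3 without monocyte replicate 1. Cell cycle genes were higher as a list (1 of 40 passing, 1 when adjusted over the list alone, camera adjusted p = 6.99e-11, adjusted p = 0.462 with an estimated correlation), and 36 were higher without Ly6C-high TAM replicate 1 and 0 in limma without colon replicate 1. Immediate early genes were higher (3 of 26, 4 when adjusted over the list alone, camera adjusted p = 8.41e-06, adjusted p = 0.468 with an estimated correlation). Lipid genes moved both ways (4 of 33 higher and 3 lower, 5 and 5 when adjusted over the list alone, camera adjusted p = 0.12), with the cholesterol exporter Abca1 higher (3.01). The other genes with the largest changes that the naming rule allowed included AA467197 (6.04 ± 0.34), the prostaglandin dehydrogenase Hpgd (-3.85), the lectin receptor Klrb1f (-3.71) and Adgre4 (-3.50). Chil1 (-4.29 ± 0.90) was also among them, but lost its call without any of 5 arrays.

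The 2 tumour differences, which compare different arrays but come from the same fit, had 159 genes higher in both. Independent lists of those sizes would share 16.5 (Fisher's exact test, one-sided, p = 1.36e-113). They had 35 genes lower in both, where independent lists would share 12.9 (Fisher's exact test, one-sided, p = 9.69e-08). In opposite directions, 15 genes were higher in F4/80-high TAM and lower in Ly6C-high TAM (9.27 for independent lists), and 12 were lower in the former and higher in the latter (22.9). Genes are not independent of each other, and both differences take each gene's spread from the same fit of all 8 arrays. The replicate differences of the 2 tumour populations also correlated across genes (0.77). The values for independent lists are therefore not a chance level, and these p-values describe only the overlap of these lists. Arg1 rose by similar amounts in both, and the interaction test gave -0.24 ± 0.20 (adjusted p = 0.582). The interaction for Col14a1 was -0.29 ± 0.19 (adjusted p = 0.465).

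The 3 remaining comparisons set each tumour population against the other source tissue, and the reference populations against each other. F4/80-high TAM had 981 genes higher and 509 lower than spleen monocytes, and 790 and 863 after median centring, which moved the median of all genes by -0.23. The counts were 394 and 207 without monocyte replicate 2. Among the genes that the naming rule allowed, Spp1 (7.30 ± 0.15), Arg1 (6.36 ± 0.14) and the endocytic adaptor Dab2 (6.19 ± 0.64) were highest. Serpinb10 (-7.94 ± 0.24), Adgre4 (-6.25) and the ribonuclease Ear2 (-5.76) were lowest. Col14a1 was 17-fold higher (4.08 ± 0.14, limma adjusted p = 5.46e-05). Cell cycle genes were higher (22 of 40, 38 when adjusted over the list alone, camera adjusted p = 2.64e-17, adjusted p = 0.465 with an estimated correlation), and classical monocyte genes lower (12 of 24, 15 when adjusted over the list alone, camera adjusted p = 1.86e-13, adjusted p = 0.0706 with an estimated correlation).

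Ly6C-high TAM had 587 genes higher and 892 lower than colon macrophages, with a range of 391 (without colon replicate 1) to 1182 (without Ly6C-high TAM replicate 1) higher and 455 (without colon replicate 2) to 999 (without Ly6C-high TAM replicate 2) lower. Median centring moved the median of all genes by 0.12 and gave 837 higher and 858 lower. The epithelial covariate, which also alters other differences from the colon arrays, gave 2185 and 1343. Among the genes that the naming rule allowed, the chitinase-like gene Chil3 (6.93 ± 1.37), Arg1 (6.41 ± 0.14) and Trem1 (5.86) were highest. Apol7c (-7.12 ± 0.79), Mptx1 (-6.84) and Clca1 (-6.00) were lowest. Chil3 lost its call without either colon or monocyte array (adjusted p of up to 0.118). Of the sort markers, Ly6c2 (2.83) and Ccr2 (1.61) were higher and Adgre1 (-1.34) and Cx3cr1 (-1.98) lower. Of 38 interferon-response genes, 32 were higher and 0 lower (34 and 0 when adjusted over the list alone, camera adjusted p = 7.17e-35, adjusted p = 0.246 with an estimated correlation). Of 24 classical monocyte genes, 15 were higher and 0 lower (16 and 0 when adjusted over the list alone, camera adjusted p = 4.66e-12, adjusted p = 0.1 with an estimated correlation).

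Colon macrophages had 1486 genes higher and 857 lower than spleen monocytes, and 1259 and 1655 after median centring, which moved the median of all genes by -0.28. The counts were 702 and 556 without monocyte replicate 2, and 573 and 914 with the epithelial covariate. Resident gut macrophage genes were higher (18 of 31, 22 when adjusted over the list alone, camera adjusted p = 2.37e-15, adjusted p = 0.0432 with an estimated correlation), and so was MHC class II presentation (5 of 12, camera adjusted p = 0.000115, adjusted p = 0.437 with an estimated correlation), with H2-Ab1 at 1.10. Interferon-response genes were lower (24 of 38 lower and 1 higher, the same when adjusted over the list alone, camera adjusted p = 3.53e-14, adjusted p = 0.315 with an estimated correlation). Serpinb10 (-8.10 ± 0.24), Chil3 (-7.24 ± 1.37) and Ifitm6 (-6.79 ± 0.21) were lowest. The highest genes were Muc3 (6.74 ± 1.36), Mptx1 (6.59 ± 0.49) and the goblet cell gene Zg16 (6.39 ± 1.46), and 24 of 25 epithelial markers were higher (24 when adjusted over the list alone, camera adjusted p = 5.44e-17, adjusted p = 0.315 with an estimated correlation). Muc3, Zg16 and Chil3 each lost their call without either colon or monocyte array (adjusted p of up to 0.118, 0.157 and 0.0861).

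Genes higher in 1 population than in each of the 3 others numbered 7 for F4/80-high TAM, 2 for Ly6C-high TAM, 613 for colon macrophages and 229 for spleen monocytes, where simulated populations without changes gave 0. Independent lists would give 0.044, 0.0165, 2.3 and 0.329. Neither value is a chance level for these counts, because the 3 comparisons of a population share its arrays and the spread of the fit. The simulation also had no difference between any populations and noise that was independent between arrays. The smallest fold over the 3 others was 3.26 for Col14a1, 2.97 for the long noncoding RNA gene Mexis and 2.43 for Cebpzos in F4/80-high TAM. It was 4.49 for the acyltransferase Gpat3 and 2.42 for Rab44 in Ly6C-high TAM. For colon macrophages it was 96.4 for Mptx1, 64.2 for Clca1 and 62.1 for Cyp2c55, and for spleen monocytes 18.2 for Chil1, 13.1 for Klrb1f and 11.1 for Cyp2ab1. The colon arrays had the highest means of the epithelial list (10.42 and 11.16). Epithelial RNA in them could be a source of gut genes in the colon count, which was not tested. The call of Chil1 against Ly6C-high TAM was lost in several fits with an array left out. Both tumour counts were 0 without F4/80-high TAM replicate 1, and were 110 and 10 without Ly6C-high TAM replicate 2. Each of these fits left a lone array in a tumour population, so its spread came from the other populations. The colon count fell to 245 without F4/80-high TAM replicate 1 and the monocyte count to 92 without monocyte replicate 1.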

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

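The tests on marker genes of other cells and on Mela in this part were chosen only after the results were seen, and the interaction test and the tests of normalization were chosen before.

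The tumour difference of the F4/80-high cells (against colon macrophages) and that of the Ly6C-high cells (against spleen monocytes) differed for 1407 genes by the limma interaction test at an adjusted p of 0.05 or less, with the F4/80-high difference minus the Ly6C-high difference above 0 for 670 and below 0 for 737. The count was 172 without monocyte replicate 2 and 2738 without Ly6C-high TAM replicate 1. Slfn1 had a difference between the 2 of 4.85 (SE 0.39, adjusted p = 0.00386), with log2 means of 11.44 in F4/80-high TAM, 12.22 in Ly6C-high TAM, 6.46 in colon macrophages and 12.09 in spleen monocytes. The difference was 3.72 for Klrb1f, 1.51 for Spic, 1.32 for Trem1 and -1.41 for Spp1. It was -4.68 for Bgn, -4.75 for AA467197 and -5.46 for Dcn, and for the gut genes Cyp2c55, Mptx1 and Clca1 it was -6.35, -6.46 and -6.81. No biological explanation was tested for these differences, in which the tissue of the reference population differs as well.

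Among the 10864 probe sets with no gene symbol, which no comparison of the report used, a few passed the same threshold in a limma fit of their own. F4/80-high TAM and colon macrophages differed in 1, Ly6C-high TAM and spleen monocytes in 1, Ly6C-high TAM and colon macrophages in 2 and colon macrophages and spleen monocytes in 6. F4/80-high TAM and spleen monocytes differed in 121, of which 12 were higher and 109 lower in the tumour cells. The cause was not tested.

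Collagens I, III and VI (6 genes) had a median log2 difference of 1.82 (median SE 0.42) between Ly6C-high TAM and spleen monocytes, with 3 genes past the threshold. The difference was still 1.64 or more after quantile normalization and median centring. The values had already been normalised by RMA, and median centring moved the median of all genes by only -0.16. Such steps could hardly have removed the difference, so they do not test normalization as its cause. With the fibroblast marker mean as a covariate the difference was 0.14 (median SE 0.26) and 0 genes passed in limma, and the 6 genes were higher in replicate 2 than in replicate 1 by medians of 1.16 and 0.85 in Ly6C-high and F4/80-high TAM, where 23 fibroblast markers differed by 0.83 and 0.61. RNA from fibroblasts in the sorted tumour samples may therefore account for much of these collagen values. Without both tumour arrays of replicate 2, the differences were 1.43 for Col6a1, 1.32 for Col6a2 and 1.34 for Col3a1. The lone Ly6C-high TAM array of that fit still had a fibroblast list mean of 7.26, against 6.45 and 6.47 in spleen monocytes. These differences therefore do not speak against fibroblast RNA. Expression by the macrophages themselves stays open and was not tested, since the marker mean also differs between tumour and spleen and as a covariate removes part of any tumour difference.

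Col14a1 differed from those collagens. It was higher in F4/80-high than in Ly6C-high TAM by 2.03 or more after either normalization, and its values in replicate 2 differed from replicate 1 by at most 0.15, where the fibroblast markers differed by 0.61 and 0.83. The 23 fibroblast markers differed between F4/80-high and Ly6C-high TAM by medians of -0.10 in replicate 1 and -0.56 in replicate 2, and with the marker mean as a covariate Col14a1 differed by 2.11 (SE 0.14, adjusted p = 0.00196). The replicate and marker values argue against fibroblast RNA as the cause. Median centring and quantile normalization moved the median of all genes by only -0.066 and -0.046. They could hardly have removed a difference of 2.09, so they do not test normalization as the cause. Expression of Col14a1 by F4/80-high TAM is a candidate explanation, as a hypothesis found and tested on the same arrays, and its call was lost without F4/80-high TAM replicate 1 and without either monocyte array (adjusted p of up to 0.0617).

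Of the 25 epithelial markers, 100% were higher by 2-fold or more in colon macrophages than in spleen monocytes, and all 25 were higher in colon replicate 2 than in colon replicate 1. The median difference was 4.23 or more after either normalization, against 4.51 in the deposited values. Median centring and quantile normalization moved the median of all genes by only -0.28 and -0.03. They could hardly have removed this difference, so they do not test normalization as its cause. Epithelial RNA or cells in the sorted colon samples could be a source of these transcripts, but the count of 25 restates the pattern that prompted it and does not test this source apart. Uptake of epithelial cells by living macrophages stays open as well and was not tested.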

How the results depend on the processing

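The removal of both tumour arrays of replicate 2, the replicate blocks for the tumour arrays alone and with the monocyte numbers crossed, and the fibroblast and epithelial covariates were chosen only after the results were seen. The labels do not say whether the tumour replicates came from separate animals. The sex labels and Xist differ between the replicates of colon macrophages and of spleen monocytes. Between replicates, 768 genes differed 2-fold or more in F4/80-high TAM and 1536 in Ly6C-high TAM. Fewer differed in colon macrophages (371) and spleen monocytes (76). These counts argue against repeated arrays of the same RNA in the tumour populations, but the same animals or pools stay possible. With 2 arrays per population a count depends on single arrays. Without an array, the lone array of its population was assumed to vary like the others. The change of the source of the values was not run, because the columns of the other table match no sample label, and array detection calls were not used here. Leaving out the dimmest 25% of genes, leaving out the sex chromosomes and taking the mean of the probe sets kept each count of genes within 1.5 times. Over all settings, the 201 results for named genes gave 5613 values, of which 4906 kept direction and side of the threshold, 617 lost the threshold, 42 gained it and 48 changed sign. Of the list shifts called at the preset correlation in the 3 main comparisons, 1 was also called with an estimated correlation (classical monocyte genes, F4/80-high against Ly6C-high TAM) and 17, 10 and 21 were not, for F4/80-high against Ly6C-high TAM, F4/80-high TAM against colon macrophages and Ly6C-high TAM against spleen monocytes. In the same order, fry called 3, 3 and 14 of them, and without the dimmer 50% of genes 13, 7 and 18 were called, 3, 2 and 1 were not, and the others had too few genes left to be tested. The sort by Ly6C itself favours the direction of the classical monocyte list between the tumour populations. The cause was not tested unless the setting itself states it. In what follows, pairs of numbers are genes higher and lower in the population named first, "specific" means higher than in each of the 3 other populations, and the other values are log2 differences.

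With each array left out in turn, F4/80-high TAM against colon macrophages gave 291 to 788 higher and 319 to 960 lower, F4/80-high against Ly6C-high TAM 0 to 190 and 0 to 55, and Ly6C-high TAM against spleen monocytes 243 to 1680 and 123 to 856. F4/80-high TAM against spleen monocytes gave 394 to 1269 and 207 to 617, Ly6C-high TAM against colon macrophages 391 to 1182 and 455 to 999, and colon macrophages against spleen monocytes 702 to 1686 and 556 to 909. The interaction gave 172 to 2738 genes, and the specific genes were 0 to 110 (F4/80-high TAM), 0 to 10 (Ly6C-high TAM), 245 to 711 (colon) and 92 to 316 (monocytes). Some signs changed within these ranges. In F4/80-high TAM against colon macrophages, Ccr2 ran from -0.43 to 0.14 (highest without colon replicate 1), Col1a1 from -0.24 to 1.22, Col1a2 from -0.21 to 1.496, Col3a1 from -0.19 to 0.45 and Col6a3 from -0.17 to 0.67 (each collagen lowest without F4/80-high TAM replicate 2). Between the tumour populations, H2-Ab1 ran from -0.22 (without F4/80-high TAM replicate 2) to 0.29, Col1a1 from -1.49 to 0.091, Col1a2 from -1.47 to 0.23, Col6a1 from -1.05 to 0.044 and Col6a3 from -1.21 to 0.01 (highest without Ly6C-high TAM replicate 2, or for Col1a2 without F4/80-high TAM replicate 1). In Ly6C-high TAM against spleen monocytes, Ly6c2 ran from -0.21 to 0.086 and Ly6c1 from -0.12 to 0.018 (highest without Ly6C-high TAM replicate 2).

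Without both tumour arrays of replicate 2, F4/80-high against Ly6C-high TAM gave 207 and 98, with 95 and 28 specific genes for the 2 populations. Signs changed against colon macrophages for Col1a1 (-0.24), Col1a2 (-0.21), Col3a1 (-0.19) and Col6a3 (-0.17) in F4/80-high TAM, between the tumour populations for H2-Ab1 (-0.26), and against spleen monocytes for Ly6c2 (0.086) and Ly6c1 (0.018) in Ly6C-high TAM.

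The replicate block gave 18 genes higher in F4/80-high than in Ly6C-high TAM and 3 and 1 specific genes, and with it the 18, 10 and 21 list shifts of the 3 main comparisons were called. List shifts of the other comparisons were not run with it. The block pairs arrays by a number that the labels do not tie to an animal. A block for the tumour arrays alone gave 156 and 95 for F4/80-high against Ly6C-high TAM, with Ly6c2, Ly6c1, Cx3cr1 and Ccr2 among the genes gained, 36 and 22 specific genes and 4340 interaction genes. With that block, signs changed in F4/80-high TAM against colon macrophages for Cx3cr1 (0.10), Ccr2 (0.12), Col1a1 (-0.27), Col1a2 (-0.20), Col3a1 (-0.21) and Col6a3 (-0.27). The block with the monocyte numbers crossed gave 2148 interaction genes.

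The fibroblast covariate gave 246 and 121 for F4/80-high against Ly6C-high TAM, 1210 lower in F4/80-high TAM and 1356 lower in Ly6C-high TAM than in colon macrophages, 2455 interaction genes and 29 and 30 specific genes. With it, signs changed in F4/80-high TAM against colon macrophages for Cx3cr1 (0.16), Ccr2 (0.19), Col1a1 (-0.33), Col1a2 (-0.26), Col3a1 (-0.24) and Col6a3 (-0.33). They changed in Ly6C-high TAM against spleen monocytes for Adgre1 (0.32), Cx3cr1 (0.40), Ccr2 (0.47), H2-Ab1 (-0.09), Col1a1 (-0.37), Col1a2 (-0.54) and Col6a3 (-0.18). The epithelial covariate gave 2220 higher in F4/80-high TAM than in colon macrophages, 148 and 78 for F4/80-high against Ly6C-high TAM, 2185 and 1343 for Ly6C-high TAM against colon macrophages, 573 higher in colon macrophages than in spleen monocytes, 358 interaction genes and 45, 16, 280 and 117 specific genes. With it, signs changed for Muc3 (-0.76) and Zg16 (-2.06) in colon macrophages against spleen monocytes and for Pgf (0.082) in F4/80-high TAM against colon macrophages. The epithelial marker mean was far higher in the colon arrays than in the others, so this covariate also alters other differences from colon macrophages. The sex covariate, which marks 1 colon and 1 monocyte array, gave 306 and 324 for F4/80-high TAM against colon macrophages, 0 and 2 for F4/80-high against Ly6C-high TAM, 338 and 192 for Ly6C-high TAM and 608 and 303 for F4/80-high TAM against spleen monocytes. It gave 458 lower in Ly6C-high TAM than in colon macrophages, 592 interaction genes, 0, 0, 266 and 135 specific genes, and 0.01 for Ly6c2 in Ly6C-high TAM against spleen monocytes.

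Median centring gave 863 lower in F4/80-high TAM and 1655 lower in colon macrophages than in spleen monocytes, 6 specific genes for Ly6C-high TAM and 359 for monocytes, and H2-Ab1 at -0.031 between the tumour populations and -0.014 in Ly6C-high TAM against spleen monocytes. Quantile normalization gave -0.016 for Col3a1 in F4/80-high TAM against colon macrophages. Leaving out the dimmer 50% of genes, with fewer genes tested, gave 379 lower in F4/80-high TAM and 458 lower in Ly6C-high TAM than in colon macrophages, and 4 and 248 specific genes for Ly6C-high TAM and colon macrophages. The intensity trend gave 6 specific genes for Ly6C-high TAM. Array weights gave 10 genes higher in F4/80-high than in Ly6C-high TAM and 3 and 1 specific genes.

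Without moderation of the spread, counts were 203 and 164 for F4/80-high TAM against colon macrophages, 1 and 0 against Ly6C-high TAM (limma gave 1837 at an unadjusted p under 0.05) and 407 and 224 against spleen monocytes. Ly6C-high TAM gave 205 and 109 against spleen monocytes and 268 and 221 against colon macrophages, 657 genes were higher in colon macrophages than in spleen monocytes, the interaction gave 200, and 1, 0, 119 and 87 were specific. Fits of only the 2 groups gave 0 and 0 for F4/80-high against Ly6C-high TAM, 371 and 199 for Ly6C-high TAM against spleen monocytes and 351 and 341 against colon macrophages, with 0, 0, 226 and 138 specific genes.

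Without a fold limit, 1564 were higher in F4/80-high TAM than in colon macrophages, 626 lower in Ly6C-high TAM than in spleen monocytes, 1516 and 982 for F4/80-high TAM against spleen monocytes, 1203 higher in Ly6C-high TAM than in colon macrophages, 1973 lower in colon macrophages than in spleen monocytes and 441 specific to monocytes. A fold of 4 gave 96 and 370 for F4/80-high TAM against colon macrophages, 9 and 12 against Ly6C-high TAM and 386 and 130 against spleen monocytes. For Ly6C-high TAM it gave 287 and 67 against spleen monocytes and 186 and 379 against colon macrophages, for colon macrophages 750 and 213 against spleen monocytes, and 0, 1, 292 and 43 specific genes. Adjustment over all 6 comparisons gave 115 and 79 for F4/80-high against Ly6C-high TAM and 21 and 12 specific genes.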

Other observations

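The tests on Mela and on the arrays of replicate 2 in this part were chosen only after the result was seen.

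Of 40 cell cycle genes, 22 were higher in F4/80-high TAM than in spleen monocytes, 3 higher than in colon macrophages (1 without F4/80-high TAM replicate 1) and 0 by limma higher than in Ly6C-high TAM (1 when adjusted over the list alone), and the list shifts were lost with an estimated correlation (adjusted p = 0.465, 0.746 and 0.626). The mean log2 value of the list was 9.67 and 10.002 in F4/80-high TAM replicates 1 and 2, 8.03 and 9.66 in Ly6C-high TAM, 8.38 and 8.71 in colon macrophages and 7.74 in both monocyte arrays, so the 2 tumour populations differed less in replicate 2 than in replicate 1. Without both tumour arrays of replicate 2, 23 of the 40 genes were higher in F4/80-high than in Ly6C-high TAM and 23 higher than in colon macrophages, while 1 was higher and 1 lower in Ly6C-high TAM than in spleen monocytes. Of 38 interferon-response genes, 24 were lower in colon macrophages than in spleen monocytes, 32 lower than in Ly6C-high TAM and 29 lower than in F4/80-high TAM, and the list shifts were lost with an estimated correlation (adjusted p = 0.315, 0.246 and 0.592).

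Mela, which encodes a melanoma antigen of retroviral origin, had log2 values of 12.97 and 12.76 in F4/80-high TAM and 12.87 and 13.35 in Ly6C-high TAM, against 5.21 to 5.81 in the colon and spleen arrays. It passed the threshold in F4/80-high TAM against colon macrophages (limma adjusted p = 0.000157) and in Ly6C-high TAM against spleen monocytes (limma adjusted p = 0.000128), and no size of difference is given because the reference values lay below the array medians and the tumour values near the top. A second probe set of Mela read 7.56 to 7.67 in the tumour arrays and 6.47 to 6.93 in the colon and spleen arrays. Mela was higher in replicate 2 than in replicate 1 by 0.48 in Ly6C-high TAM and differed by -0.21 in F4/80-high TAM, where the epithelial and tumour cell markers differed by medians of 1.92 and 1.47. RNA from tumour cells in the sorted samples could be a source that these values leave open, because Mela lay within 0.86 of the highest value on an array and saturation would hide a difference between replicates. No biological explanation was tested.

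The differences between replicate 2 and replicate 1 correlated across genes between F4/80-high and Ly6C-high TAM (0.77), and less between colon macrophages and these populations (0.22 and 0.259) or between spleen monocytes and these populations (-0.155 and -0.108). Genes that differed 2-fold or more between replicates numbered 768 in F4/80-high TAM, 1536 in Ly6C-high TAM, 371 in colon macrophages and 76 in spleen monocytes. The 2 tumour arrays of replicate 1 correlated at 0.9832 and those of replicate 2 at 0.9878, while the replicates of F4/80-high TAM correlated at 0.9803 and those of Ly6C-high TAM at 0.9669.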
